A study of Rattus norvegicus with 15 samples.

How the data were processed

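Single-cell 3′ RNA libraries (10x Genomics chemistry) were read from 7 samples of mammary tumours of female rats that express Cas9. Per the labels' protocols, tumours were digested with collagenase I and DNase at 37 °C for 1 h, passed through a 70 µm strainer and sorted for live cells. The Nf1 tumours were sorted further into CD45-positive and CD45-negative cells. The labels date the 6 Nf1 libraries to 9/20/2023 and the Pik3caH1047R library to 6/25/2024. The remaining 8 of the 15 samples in the labels belong to no group and were not analysed here.

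The deposited values are raw UMI counts per feature and cell for barcodes already assigned to a sample, made with Cell Ranger 8.0.0, per the file headers and the submitters' processing notes. Those notes name mRatBN7.2 as the genome; no gene annotation release is stated. Every value in the deposited files is a whole number of at least 1. The files hold 25629 genes and 12 multiplexing tags, and the tags were kept out of library sizes, filters and tests. For 431 gene entries under 211 shared symbols, a symbol stands for several entries, which were kept apart by gene identifier. Cell Ranger's assignment of reads between near-identical genes was not examined, so values of single members of gene families, such as the RT1 genes, are uncertain. The Nf1 libraries shared 0 barcodes with each other, and the Pik3caH1047R library shared at most 4 with any of them; cells were kept apart by library. Values scaled to library size (CPM) were computed here from the deposited counts, with TMM-scaled library sizes in comparisons and summed UMIs as the total in cell classes and clusters.

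Cells were kept with at least 500 genes, at least 1000 UMIs and at most 20% mitochondrial UMIs, which left 23497 of 28441 cells. Over the mitochondrial limit were 25.6%, 26.2% and 29.0% of the cells of the CD45-negative libraries, 3.74%, 2.90% and 3.39% of the CD45-positive and 15.2% of the Pik3caH1047R library. Scrublet in scanpy 1.11.5, run per library with an expected doublet rate of 6%, called 662 cells (2.82%), which were removed. Counts were scaled to 10000 per cell and log-transformed. From 2000 variable genes without the members of the readout lists, standardised to at most 10, 30 principal components were taken. A graph of 20 neighbours weighted by shared neighbours was clustered with leidenalg 0.10.2 at resolution 1.0. No correction between libraries was made.

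The 37 clusters were named by 17 marker lists fixed before the data were examined, as were the comparisons, the readout lists, the alternatives and the rule for named genes. A cluster takes the name of its best list if at least 3 markers lie 1 log2 unit above the other clusters and occur in 10% of its cells. Rules that take a name away were settled after the clusters had been seen: a name is lost if the 10 leading genes hold more markers of another class, if most of them stand high in another compartment, or if UMI counts are low and no marker leads. No name was left for 2 clusters. Names end in "-like" because they rest on RNA alone. Of the list members 15 could not be matched to a symbol in the files and were not analysed here.

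UMI counts were summed over the cells of a library, or of a class within it where at least 20 cells were present. Sums were compared with edgeR 4.0.16 (TMM scaling, filterByExpr, quasi-likelihood F test) and p-values adjusted by Benjamini-Hochberg, with a threshold of 0.05. All adjusted p-values of genes come from this test unless DESeq2 is named. Standard errors were computed from the log2 fold change and the F statistic. The comparisons were CD45-positive against CD45-negative libraries; epithelial-like against fibroblast-like and luminal-like against basal-like cells of the CD45-negative libraries, with the tumour as a block; and the Pik3caH1047R library against the Nf1 libraries in epithelial-like, fibroblast-like, macrophage-like and T-like cells. In these last 4 the single library is assumed to vary like the Nf1 libraries. The first comparison was fitted without a block. Deviations from the group means correlated at 0.207, 0.231 and 0.131 between libraries of the same tumour number and at -0.21 to 0.0620 between others. The numbers were thus taken to pair the libraries, from the data and not from a statement in the labels. Deviations within a fraction sum to 0 and so depend on each other, which makes this weak evidence of pairing.

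The 13 readout lists cover hormone receptors and targets, milk and alveolar genes, Ras-MAPK output, FOXO targets, sterol and lipid synthesis, glycolysis and hypoxia, the cell cycle, mesenchymal and matrix genes, MHC and interferon, T cell activation and checkpoints, tumour macrophage genes, dissociation stress, and growth factor receptors and ligands. They were tested with camera in limma 3.58.1 with a preset inter-gene correlation of 0.01, again with an estimated correlation, and with fry, each adjusted over the lists of a comparison. With an estimated correlation no list passed in any comparison, even where that correlation lay near or below the preset. Calls lost in that setting thus do not by themselves show correlated genes. Where the estimate lay far above the preset, p-values with the preset can be too small. Members were also adjusted over their own list alone. Edited and driver genes were counted without a list test. Named genes are up to 4 members per list with the smallest adjusted p-values, the 5 largest rises and 5 largest falls among called genes with a mean of at least 10 CPM, and always 8 genes fixed beforehand, among them Esr1, Pgr, Prlr, Erbb2, Nf1 and Pik3ca; the text gives a part of them, and some are not reported here. Where a group had 0 counts, the fold is given as at least the ratio to 3 counts. For the 8 fixed genes, an edgeR interaction test, added after seeing the data, asked whether the difference between genotypes depends on the cell class.

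Class shares were compared between fractions by an exact two-sided permutation test. Shares of cells with a UMI of a gene were taken after thinning each cell to 2000 UMIs, and cells with fewer were left out. Intervals of shares are exact (Clopper-Pearson) 95% intervals. Beside a share of 0 the limit given is not such an interval but the share that 3 cells would make. With 1091 cells used, the Pik3caH1047R library is the least precise; its sums held 2769704 UMIs for epithelial-like, 548335 for fibroblast-like, 1025154 for macrophage-like and 1503458 for T-like cells.

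The edgeR test was tested on simulated counts with the depth and spread of each comparison. Of genes changed 2-fold and 4-fold it found 67% and 90% for the fractions (16613 genes), 81% and 100% for luminal-like against basal-like cells (15138 genes), 25% and 61% for the genotypes in epithelial-like (16928 genes), 25% and 67% in macrophage-like (13975 genes) and 46% and 87% in T-like cells (12128 genes). The false share of the calls was 6%, 9.5%, 11.3%, 8% and 5.7%. The comparisons with fibroblast-like cells were not simulated.

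Alternatives were DESeq2 1.42.0 size factors and the DESeq2 test, no expression filter, no cell filter, at most 10% mitochondrial UMIs, doublets kept, resolutions 0.5 and 2.0, readout genes kept in clustering, class members without UMIs of another compartment, sums thinned to the Pik3caH1047R total, equal cell numbers, the other block, each replicate left out, and thinning to 1000 UMIs or none. Added after seeing the data were luminal-like cells alone, clusters rich or low in Csn3 (limit 1000 CPM), Pik3caH1047R cells whose first tag has at least 2 times the counts of the second, T-like with NK-like cells, fractions without cells of the other compartment, and leaving out replicates for the Esr1 share. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, scikit-learn 1.9.0, igraph 0.11.9, matplotlib 3.10.9, R 4.3.3 and the R package data.table (version 1.17.8) were used.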

Results

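Messenger RNA was counted in single cells from rat mammary tumours by 3′ sequencing of unique molecular identifiers (UMIs). The tumours were raised in female rats that express Cas9, by vectors placed in the mammary ducts. One vector targeted Nf1, which encodes neurofibromin, a protein that switches off Ras. The other carried Pik3caH1047R, an activated form of the catalytic subunit of phosphoinositide 3-kinase, with the protein change H1047R. Tissue from 3 Nf1 tumours was sorted into a CD45-negative and a CD45-positive fraction, which gave 3 libraries of each; CD45, the product of Ptprc, marks blood-derived cells. Live cells of Pik3caH1047R tumour tissue gave 1 library, sorted without a CD45 gate and on another date. A further 8 samples in the labels belong to no group and were not analysed here.

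The CD45-negative libraries held 4180, 5882 and 5536 cells with 50992723, 67071044 and 60749715 UMIs. In the CD45-positive libraries there were 3609, 2867 and 5043 cells with 35578481, 29089674 and 57977803 UMIs. The Pik3caH1047R library held 1324 cells with 8074389 UMIs, and its median of 4331 UMIs per cell was lower than the medians of the other libraries, which ran from 7857 to 10017. After filtering, 22835 of 28441 cells were used. The labels number the 3 Nf1 tumours but do not say whether they came from separate rats, so p-values measure the spread between these samples. With 1 Pik3caH1047R library, genotype and date cannot be told apart in the comparisons with the Nf1 libraries, and the gate differs as well. The labels do not say whether its 240 cells with tag 302 highest belong to the same sample as the 1083 cells with tag 301 highest, and 776 of its 1324 cells have a first tag with at least 2 times the counts of the second. Intervals and floors cover counting error only.

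The targeted genes were read first. Nf1 (ENSRNOG00000013780) stood at 254.6, 219.7 and 240.5 CPM (UMI counts scaled to library size) in the CD45-negative libraries and at 132.1, 139.8 and 144.5 CPM in the CD45-positive ones. Pik3ca (ENSRNOG00000056371) stood at 106.1, 103 and 102.5 CPM in the former and 94.84, 85.53 and 82.03 CPM in the latter. In epithelial-like cells of the Pik3caH1047R library Nf1 stood at 222 CPM and Pik3ca at 150.5 CPM. Tags at the 3′ end of a transcript do not read the edited site, so these levels check neither edit. Ptprc, the sort marker, averaged 856.6 CPM in the CD45-positive and 12.86 CPM in the CD45-negative libraries, in the direction the labels give.

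Luminal-like and basal-like epithelial cells made up nearly all of the CD45-negative fraction, while macrophage-like and T-like cells had the highest mean shares in the CD45-positive one. Epithelial-like cells were 97.4 ± 1.17% (SD, n = 3) of the CD45-negative and 4.15 ± 0.877% (n = 3) of the CD45-positive cells. Among the CD45-negative cells 70.8 ± 5.004% were luminal-like and 26.6 ± 5.36% basal-like. The CD45-positive cells were 40.4 ± 10.3% macrophage-like, 18.2 ± 8.82% T-like, 8.23 ± 3.55% NK-like, 9.68 ± 0.992% dendritic-like and 8.16 ± 1.62% plasmacytoid-dendritic-like. T-like and NK-like cells together were 40.5%, 20.8% and 17.8% of the CD45-positive libraries. Neutrophil-like cells numbered 36, 396 and 328 in these libraries, and B-like cells 67, 1 and 1. Mast-like cells were the class nearest to equal, at 0.314 ± 0.127% of the CD45-negative and 0.443 ± 0.0236% of the CD45-positive cells. The exact two-sided permutation test gave p = 0.1, the smallest that 3 against 3 libraries allow, for each class except fibroblast-like cells at p = 0.4 and mast-like cells at p = 0.3.

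In the Pik3caH1047R library, T-like and NK-like cells together were the largest part, at 50.0% of 1091 cells (exact 95% interval 46.9 to 53.0%). Epithelial-like cells made up 18.2% (15.9 to 20.6%), and 7 of these 198 cells were basal-like, against 21.4% to 32.0% of the epithelial-like cells in the Nf1 CD45-negative libraries. Macrophage-like cells were 14.4% (12.4 to 16.6%), endothelial-like cells 7.88% (6.35 to 9.64%) and fibroblast-like cells 4.40% (3.26 to 5.79%). No test was run against this single library, whose gate differs. Without cell filters the epithelial-like share of the library was 8.94%.

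**Figure D1:**
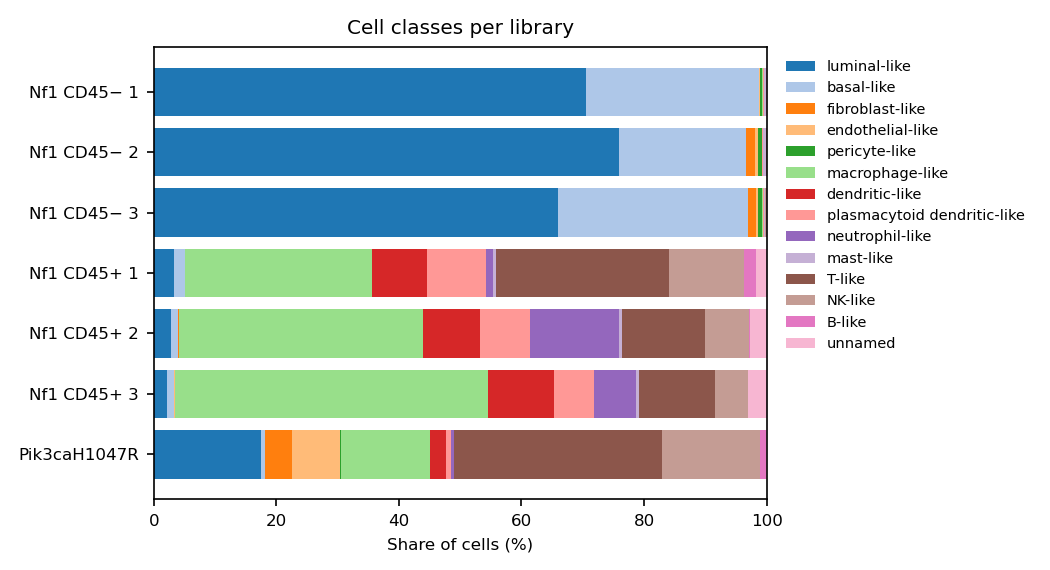
Share of cells (%) per class in each of the 7 libraries, as stacked bars. Luminal-like and basal-like cells fill 97.4 ± 1.17% (SD, n = 3) of the Nf1 CD45-negative libraries, and T-like and NK-like cells 50.0% of the Pik3caH1047R library.

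The series title names oestrogen-receptor-positive cancer, so the question was which cells carry Esr1, the gene of oestrogen receptor alpha (ENSRNOG00000019358). With every cell thinned to 2000 UMIs, an Esr1 UMI was found in 17.9 ± 0.460% (SD, n = 3) of luminal-like but 0.974 ± 0.608% of basal-like cells of the Nf1 CD45-negative libraries. Over all epithelial-like cells the Nf1 share was 12.8 ± 1.39%. The Pik3caH1047R library had Esr1 in 10.8% of its epithelial-like cells (21 of 194; exact 95% interval 6.83 to 16.1%) and in 10.7% of its luminal-like cells (20 of 187; 6.66 to 16.03%). Background was read in macrophage-like cells, at 0.713 ± 0.0301% in the Nf1 CD45-positive libraries and 0 of 136 in the Pik3caH1047R library, which allows up to 2.21%. For Nf1 this background comes from other libraries than the luminal-like share. Median depths before thinning were 12383.5, 12002 and 11699 UMIs in Nf1 and 12770.0 UMIs in Pik3caH1047R luminal-like cells, against 8345, 9491 and 10444 UMIs and 5448 UMIs in macrophage-like cells. Fibroblast-like cells of Nf1 tumours 2 and 3 also held Esr1, in 6 of 63 and 12 of 48 cells. Endothelial-like cluster 34, with 59 of its 60 cells from the Pik3caH1047R library, held 110.3 CPM of Esr1 and 441.3 CPM of Prlr, against 49.12 and 1186 CPM in the luminal-like cells of that library. Without cell filters the Pik3caH1047R epithelial-like share was 2.59%, and with finer clusters it was 19.7%. The luminal-like share of that library with finer clusters was 10.8%, near its main value. Thinning was drawn at random for each class separately, so the 19.7% is not told apart from the draw.

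Progesterone receptor (Pgr) UMIs were found in 27.0 ± 6.87% of Nf1 luminal-like cells and 5.88% of Pik3caH1047R ones. Prolactin receptor (Prlr) UMIs were found in 69.9 ± 6.43% and 34.8% of these cells. In T-like cells of the Nf1 CD45-positive libraries, which serve as background, the shares were 1.72 ± 0.491% for Pgr and 11.6 ± 2.94% for Prlr, at median depths of 5943, 6492 and 6964 UMIs. This background comes from other libraries than the Nf1 luminal-like shares. In the CD45-negative libraries basal-like cells stood at 6.39 ± 0.605% for Pgr and 8.52 ± 0.536% for Prlr. In Pik3caH1047R T-like cells both shares were 0, at a median depth of 3790.0 UMIs.

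**Figure D2:**
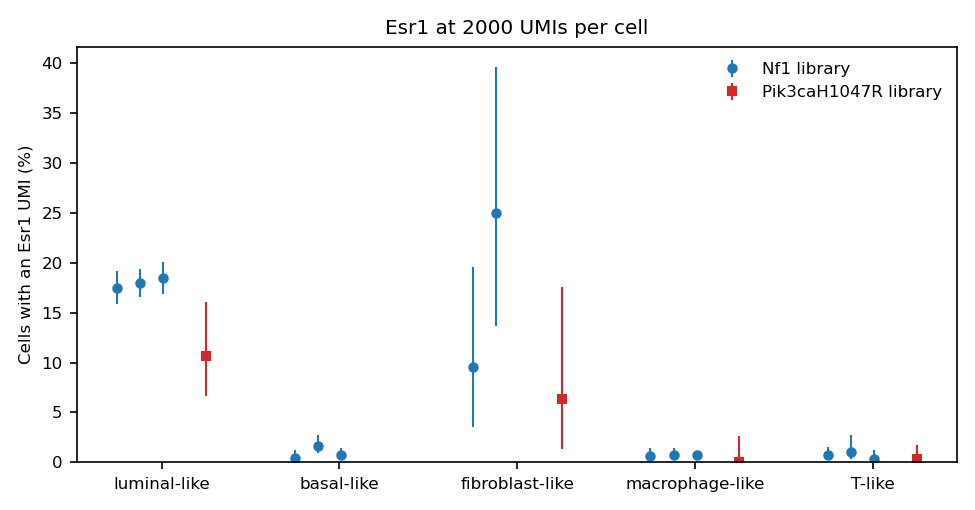
Share of cells (%) with an Esr1 UMI after thinning to 2000 UMIs, by class, with a point per library and exact 95% intervals. Nf1 luminal-like cells average 17.9%, and basal-like cells 0.974%.

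The first comparison asked which transcripts part the CD45-positive from the CD45-negative fraction of the Nf1 tumours (3 against 3 libraries). Transcripts of antigen presentation were far higher in the CD45-positive fraction: RT1-Da, a class II chain, by 5.86 ± 0.10 (log2 ± SE) and Cd74, the invariant chain that escorts class II, by 5.56 ± 0.09, both at adjusted p = 3.1e-07. Havcr2, which encodes the checkpoint receptor TIM-3, was higher by 6.15 ± 0.20 (2.6e-06). The hormone receptors were lower: Esr1 at -2.74 ± 0.25 (0.000107), Pgr at -2.66 ± 0.40 (0.00114) and Prlr at -2.86 ± 0.20 (3.6e-05). Nf1 fell by 0.78 ± 0.07 (0.000108), while Pik3ca stood at -0.25 ± 0.07 (0.0129).

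By edgeR, 11924 of 16613 genes passed, 6006 higher and 5918 lower in the CD45-positive fraction. These libraries hold different cells. Epithelial-like cells were 97.4% of the CD45-negative and 4.15% of the CD45-positive fraction, and macrophage-like cells 0.0776% and 40.4%. The list calls below thus compare cell types and show no regulation within one. Whether the class shares account for each list in full was not tested. Of 27 measured MHC and interferon genes 25 rose and 1 fell, and 20 of 20 T cell activation genes rose, with the same counts adjusted over the list alone. The camera test gave adjusted p = 1.91e-07 for the first list (0.147 with an estimated correlation) and 3.05e-06 for the second (0.530 with an estimated correlation). Tumour macrophage genes had 14 of 19 higher and 3 lower (14 and 4 adjusted over the list alone; adjusted p = 0.0276, and 0.530 with an estimated correlation), led by Mmp12, a macrophage elastase, at 5.96 ± 0.14 (9.54e-07). Cell cycle genes rose in 20 of 29 with none lower, the same adjusted over the list alone (0.00108, and 0.530 with an estimated correlation), among them Mcm5 at 0.97 ± 0.09 (0.00013).

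Of the other lists called by camera, 5 were lower and 1 higher in the CD45-positive fraction. Hormone receptors and targets fell in 16 of 22 and rose in 4 (0.00228, and 0.530 with an estimated correlation), with Tfap2c, a luminal transcription factor, at -2.51 ± 0.12 (8.59e-06). Growth factor receptors and ligands fell in 16 of 22 and rose in 5 (0.00228, and 0.147 with an estimated correlation), with Erbb3 at -2.22 ± 0.06 (1.46e-06). Sterol and lipid synthesis genes fell in 15 of 20 and rose in 1 (0.00191, and 0.530 with an estimated correlation), Sqle among them at -1.11 ± 0.08 (3.59e-05). Ras-MAPK output genes fell in 12 of 19 and rose in 3 (0.0152, and 0.530 with an estimated correlation), and milk and alveolar genes fell in 9 of 16 and rose in 1 (0.0276, and 0.530 with an estimated correlation). Dissociation stress genes rose in 11 of 15 and fell in 1 (0.0276, and 0.530 with an estimated correlation). Counts adjusted over the list alone were the same for these 6 lists.

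Members of the other lists moved both ways without a call by camera. FOXO targets had 8 higher and 5 lower of 16 (adjusted p = 0.522), glycolysis and hypoxia genes 7 higher and 4 lower of 21 (0.486), each the same adjusted over the list alone. Matrix genes had 5 higher and 12 lower of 24 (5 and 10 adjusted over the list alone; 0.255), and with the tumour number as a block this list passed at 0.0430 (0.389 with an estimated correlation). Of 12 edited and driver genes 4 rose and 4 fell, the same adjusted over the list alone. Among genes with a mean of at least 10 CPM the largest rises were Olr1 at 6.99 ± 0.83 (0.000385) and Acod1 at 6.99 ± 1.15 (0.00168). The largest falls were Hpgd, which degrades prostaglandins, at -3.21 ± 0.54 (0.00183) and Lefty1 at -3.17 ± 0.52 (0.0017). The small fall of Pik3ca did not pass without library pair 2 (-0.24, adjusted p = 0.117) or pair 3 (-0.21, 0.0888), over a range of 0.0049 to 0.117 among the alternatives. With the tumour number as a block 11687 genes passed, 11422 of them in both fits.

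The next comparison asked whether Esr1 and its targets belong to epithelial-like or fibroblast-like cells of the CD45-negative fraction (3 against 2 sums, tumour as a block). Tumour 1 gave no fibroblast-like sum, so with the block the contrast rests on tumours 2 and 3. The p-values of this fit hold little of the spread between tumours and are weak evidence. Esr1 itself did not pass, at -0.03 ± 0.19 (adjusted p = 0.915), with 79.1 CPM in epithelial-like and 81.3 CPM in fibroblast-like cells. The epithelial-like sums include basal-like cells. Luminal-like cells alone averaged 105.5 CPM of summed UMIs, against 83.05 CPM in fibroblast-like cells. Prlr was higher in epithelial-like cells by 4.10 ± 0.16 (4.25e-135), Pgr by 1.81 ± 0.22 (3.03e-15) and Areg, an oestrogen-induced ligand of the epidermal growth factor receptor, by 4.81 ± 0.20 (2.95e-124). Igfbp4, a binding protein of insulin-like growth factors, was lower by 5.75 ± 0.15 on the log2 scale, that is 48.4 against 2799 CPM. Nf1 at 0.34 ± 0.15 (0.074) and Pik3ca at -0.04 ± 0.17 (0.875) did not pass. Tumour 1 gave 0 fibroblast-like cells of 2973, which allows a share of up to 0.101%.

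In this fit 5364 of 16278 genes passed, 2856 higher and 2508 lower in epithelial-like cells. Matrix genes fell in 23 of 25 with none higher (1 higher and 23 lower adjusted over the list alone; adjusted p = 3.17e-19, and 0.533 with an estimated correlation). Their leading members Col3a1 (-10.66 ± 0.21) and Col1a1 (-10.54 ± 0.19) also named the fibroblast-like cluster and are no independent result. Milk and alveolar genes rose in 12 of 15 with none lower, the same adjusted over the list alone (0.000116, and 0.533 with an estimated correlation), with Lcn2 at 3.42 ± 0.15 (6.32e-111) and Csn3, kappa-casein, at 3.46 ± 0.16 (3.76e-107). Sterol genes rose in 14 of 20 and fell in 1 (16 and 1 adjusted over the list alone; 0.000237, and 0.533 with an estimated correlation). Cell cycle genes rose in 21 of 29 with none lower (25 and 0 adjusted over the list alone; 1.96e-07, and 0.575 with an estimated correlation), with Cenpf at 2.89 ± 0.31 (4.5e-19).

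Of 15 stress genes 11 rose with none lower, the same adjusted over the list alone (0.000116, and 0.533 with an estimated correlation), with Fos at 2.55 ± 0.18 (1.09e-45). FOXO targets rose in 10 of 16 and fell in 2, the same adjusted over the list alone (0.0195, and 0.533 with an estimated correlation), with Txnip at 1.68 ± 0.17 (2.71e-22). The hormone list was split, 11 higher and 5 lower of 21 (11 and 6 adjusted over the list alone; 0.105). Growth factor genes split 14 and 7 of 22 (0.0668), glycolysis genes 11 and 3 of 21 (0.0668), and Ras-MAPK output genes 6 and 7 of 19 (0.660). MHC and interferon genes split 6 and 7 of 26 (0.660), tumour macrophage genes 4 and 6 of 19 (0.660), and 1 of 15 T cell genes rose (0.973). For these 6 lists the counts were the same adjusted over the list alone. Of 12 edited and driver genes 1 rose and 1 fell (0 and 1 adjusted over the list alone). Fibin was at least 1431-fold lower against a floor of 3 counts over the group. Marker genes such as Lum helped to form the clusters and are not results.

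This fit had 1 residual degree of freedom, so its spread is pooled across genes, and DESeq2 called 3457 genes. Without the tumour block 5570 genes passed, 4810 of them in both fits.

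Luminal-like cells were then compared with basal-like cells of the same 3 CD45-negative libraries (tumour as a block), to place hormone response among epithelial cells. Luminal-like cells carried the hormone receptors: Esr1 rose by 4.72 ± 0.10 (adjusted p = 9.65e-06; 104.5 against 3.91 CPM), Prlr by 5.28 ± 0.07 (3.86e-06) and Pgr by 2.59 ± 0.24 (0.0006). Areg rose by 5.67 ± 0.07 (2.42e-06) and Foxa1, a pioneer factor for oestrogen receptor binding, by 4.75 ± 0.10 (8.54e-06). Dusp6, a phosphatase of ERK, at -2.62 ± 0.07 (1.21e-05) and Etv4 at -2.89 ± 0.08 (1.47e-05) were lower in luminal-like cells. Nf1 fell by 1.22 ± 0.05 (4.22e-05), and Pik3ca at 0.04 ± 0.05 (0.571) did not pass. Erbb2 rose by 2.01 ± 0.08 (3.63e-05).

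By edgeR 9049 of 15138 genes passed, 4581 higher and 4468 lower in luminal-like cells. The classes were made by clustering these same cells, so this count was bound to be large. Hormone receptors and targets rose in 15 of 20 and fell in 3 (16 and 3 adjusted over the list alone; adjusted p = 0.000375, and 0.474 with an estimated correlation). Sterol genes rose in 17 of 20 and fell in 2 (2.78e-05, and 0.479 with an estimated correlation), with Srebf1, a regulator of lipid synthesis, at 2.61 ± 0.08 (1.71e-05). Milk and alveolar genes rose in 12 of 14 and fell in 1 (0.00155, and 0.479 with an estimated correlation), with Csn1s2b, a casein, at 4.68 ± 0.19 (4.01e-05), Xdh at 3.84 ± 0.21 (9.2e-05) and Elf5, an alveolar transcription factor, at 4.39 ± 0.29 (0.000176). Ras-MAPK output genes fell in 13 of 19 and rose in 2 (0.00155, and 0.474 with an estimated correlation). For these 3 lists the counts were the same adjusted over the list alone.

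Glycolysis and hypoxia genes fell in 12 of 21 and rose in 4 (0.0367, and 0.479 with an estimated correlation), with Hk1, a hexokinase, at -1.46 ± 0.06 (4.22e-05). Of 15 stress genes 10 rose and 3 fell (0.0246, and 0.479 with an estimated correlation), both lists with the same counts adjusted over the list alone. Matrix genes fell in 13 of 24 and rose in 3 (3 and 14 adjusted over the list alone; 0.0272, and 0.474 with an estimated correlation), with Snai2, a transcription factor of basal cells, at -6.72 ± 0.09 (3.57e-06). Without the tumour block these 3 lists did not pass, at 0.115, 0.0662 and 0.0633. MHC and interferon genes rose in 13 of 25 and fell in 6 (14 and 6 adjusted over the list alone; 0.138), Cxcl9 among the latter at -6.92 ± 0.20 (1.48e-05). Cell cycle genes rose in 3 and fell in 7 of 29 (0 and 4 adjusted over the list alone; 0.528).

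Growth factor genes rose in 11 and fell in 8 of 21 (0.460), Erbb4 at 4.86 ± 0.07 (3.86e-06) against Nrg1, its ligand, at -5.13 ± 0.10 (6.93e-06). FOXO targets rose in 9 and fell in 6 of 16 (0.557), and 1 of 13 T cell genes rose and 3 fell (0.359). These counts were the same adjusted over the list alone. Tumour macrophage genes rose in 2 and fell in 5 of 19 (2 and 4 adjusted over the list alone; 0.359), Apoe, which also lies outside macrophages, at -3.80 ± 0.04 (2.42e-06). Of 12 edited and driver genes 3 rose and 5 fell, the same adjusted over the list alone. Glycam1, a milk mucin, rose by 5.84 ± 0.90 (0.00348), and Ism1 fell by 7.75 ± 0.14 (6.27e-06). Ism1 is a leading gene of a basal-like cluster, so its fall is no independent result. With luminal-like clusters low in Csn3 alone, Csn1s2b at 0.59 (adjusted p = 0.257, in a range of 2.45e-81 to 0.257), Xdh at 0.08 (0.756, in a range of 4.55e-54 to 0.756) and Elf5 at 0.00 (0.995, in a range of 1.72e-54 to 0.995) did not pass. Csn3 is itself a milk gene, and the clusters 0 and 21 left out held 285.8 and 264.8 CPM of Elf5. The loss was thus largely set by the choice of clusters. Without the tumour block 9145 genes passed, 8722 of them in both fits.

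**Figure D3:**
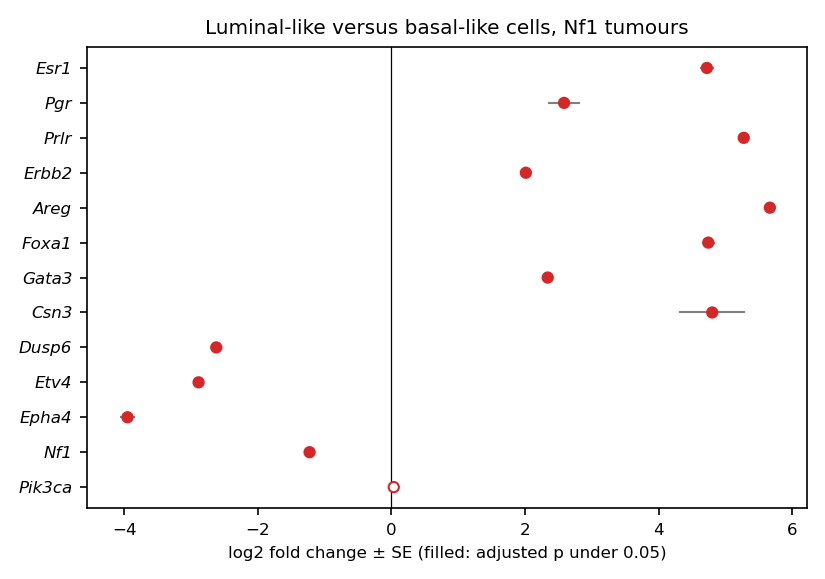
Log2 fold change with SE of named genes, luminal-like against basal-like cells of 3 Nf1 libraries, where filled points passed the test. Esr1 stands at 4.72 and Dusp6 at -2.62.

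Epithelial-like cells of the Pik3caH1047R library (198 cells, 2769704 UMIs) were set against those of the 3 Nf1 CD45-negative libraries (2936, 4012 and 3599 cells). The spread comes from the Nf1 libraries, and the lone library is assumed to vary like them. Milk genes were far higher in the Pik3caH1047R cells: Csn2, beta-casein, by 11.48 ± 1.60 (adjusted p = 0.0114), Wap, whey acidic protein, by 8.62 ± 0.61 (0.00422) and Elf5 by 2.96 ± 0.41 (0.0112). In the luminal-like cells of this library 99.86% of Csn2 UMIs lay in 79 of 191 cells, so this is not a level of the whole class. The stress gene Zfp36 was higher by 4.99 ± 0.19 (0.00248; 552 against 17.4 CPM). Ccnd1, cyclin D1, was lower at -2.94 ± 0.13 (0.00289), as were Dusp6 at -2.35 ± 0.17 (0.00423) and Areg at -5.47 ± 0.43 (0.00483). Basal-like cells were 21.4% to 32.0% of the Nf1 but 3.54% of the Pik3caH1047R epithelial-like cells. Dusp6, Ras-MAPK output and glycolysis genes were lower in luminal-like than in basal-like cells above. Their values here thus carry this difference in make-up too.

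Nf1 at -0.20 ± 0.11 (0.242) did not pass, and Pik3ca was higher by 0.45 ± 0.07 (0.0136). Esr1 stood at -0.59 ± 0.25 (0.143; 50.8 against 76.5 CPM), Pgr at -1.98 ± 0.58 (0.0633) and Prlr at -0.15 ± 0.15 (0.5). The fall of Pgr passed in 6 of 16 alternatives, among them DESeq2 (3.67e-05) and leaving out Nf1 replicate 2 (0.0256), in a range of 3.67e-05 to 0.138. Erbb2 was higher by 0.99 ± 0.17 (0.0174). Without Nf1 replicate 3, Pik3ca (0.45, 0.0512) and Erbb2 (1.008, 0.053) did not pass, nor did Erbb2 without cell filters (0.48, 0.171), in ranges of 0.00726 to 0.0512 and 0.00101 to 0.171 over the alternatives. In luminal-like cells alone, Esr1 at -1.02 (0.0156, in a range of 0.0109 to 0.737) and Prlr at -0.59 (0.0236, in a range of 0.00295 to 0.92) passed; 3.54% of the epithelial-like cells of this library were basal-like. The luminal-like cells differ in make-up, since 53.4% and 27.2% of the Pik3caH1047R ones lay in clusters 0 and 36, against 26.3% to 40.1% and 0 in the Nf1 CD45-negative libraries. In the milk gene clusters alone Esr1 stood at 0.83 (0.282) and Prlr at 0.05 (0.92). Prlr stood at 0.31 (0.21) with finer clusters and at 0.25 (0.285) in cells with a clear leading tag. Without cell filters Esr1 (-2.88, 0.0109) and Prlr (-2.90, 0.00295) were lower.

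In this comparison 6046 of 16928 genes passed, 2947 higher and 3099 lower in the Pik3caH1047R cells. Milk and alveolar genes rose in 12 of 15 with none lower (14 and 0 adjusted over the list alone; adjusted p = 5.20e-07, and 0.549 with an estimated correlation), Kit at 2.65 ± 0.16 (0.00342) and Xdh at 2.72 ± 0.32 (0.00847) among them. Stress genes rose in 13 of 15 with none lower, the same adjusted over the list alone (3.57e-08, and 0.549 with an estimated correlation), Jund at 1.63 ± 0.07 (0.00289) among them. Cell cycle genes fell in 14 of 29 with none higher (0 and 18 adjusted over the list alone; 0.000104, and 0.549 with an estimated correlation), Hells at -1.61 ± 0.17 (0.00731) and Mcm7 at -1.05 ± 0.12 (0.00764) among them. Glycolysis and hypoxia genes, to which the basal-like share given above applies, fell in 14 of 21 and rose in 1 (2 and 14 adjusted over the list alone). By camera their adjusted p was 0.000557 (0.549 with an estimated correlation), and Egln3 at -2.42 ± 0.18 (0.00456) was among them.

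Matrix genes rose in 11 of 24 and fell in 1 (11 and 3 adjusted over the list alone; 0.000897, and 0.549 with an estimated correlation). Col3a1 stood at 232.3 CPM in the epithelial-like cells of this library, at 122.3 CPM in its macrophage-like and 204.9 CPM in its T-like cells, and 4.40% of its cells were fibroblast-like. Whether matrix transcripts outside fibroblast-like cells were free RNA was not tested. MHC and interferon genes rose in 11 of 26 and fell in 3 (11 and 4 adjusted over the list alone; 0.0101, and 0.549 with an estimated correlation), Cd74 at 2.27 ± 0.07 (0.00151) among them. Ptprc stood at 47.0 CPM in these cells against 10.4 CPM in the Nf1 ones, in a library with 50.0% T-like and NK-like cells. The fall of Cxcl9, at -5.62 ± 0.33 (0.00345), did not pass in luminal-like cells alone (-0.60, adjusted p = 0.45, in a range of 1.16e-28 to 0.597).

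Other lists had no call by camera, though fry called FOXO targets (adjusted p = 0.0198), tumour macrophage (0.0198), T cell (0.0320) and growth factor genes (0.0320), all as higher. Ras-MAPK output genes, to which the basal-like share given above applies, fell in 10 and rose in 3 of 19 (5 and 11 adjusted over the list alone). By camera their adjusted p was 0.0585, and Phlda1 rose by 1.81 ± 0.10 (0.0034). FOXO targets rose in 7 and fell in 1 of 16 (8 and 1 adjusted over the list alone; 0.0923), Klf6 by 4.03 ± 0.22 (0.00312). Hormone receptors and targets rose in 4 and fell in 6 of 20 (4 and 8 adjusted over the list alone; 0.375), with Wnt4 at -1.82 ± 0.10 (0.00333), Rerg at 2.03 ± 0.13 (0.00356) and Tbx3 at -1.23 ± 0.08 (0.00382). Sterol genes rose in 5 and fell in 7 of 20 (7 and 9 adjusted over the list alone; 0.401), and growth factor genes 7 and 7 of 22 (9 and 9 adjusted over the list alone; 0.385). T cell genes rose in 4 and fell in 2 of 15 (0.375), tumour macrophage genes 7 and 2 of 19 (0.375), and edited and driver genes 3 and 3 of 12, all the same adjusted over the list alone. Upk3a was at least 326-fold lower, with 0 counts in the Pik3caH1047R cells.

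Leaving out Nf1 replicate 3 gave 4005 genes and leaving out replicate 2 gave 4113 genes past the threshold. With the clusters rich in milk genes compared alone, Wnt4 at -0.11 (adjusted p = 0.863, in a range of 8.62e-12 to 0.863), Tbx3 at -1.62 (0.239, in a range of 5.87e-08 to 0.239), Areg at -3.69 (0.052, in a range of 1.57e-52 to 0.052) and Upk3a (0.126, in a range of 7.85e-07 to 0.126) did not pass. The fold of Wnt4 was thus near 0 in these clusters, while those of Tbx3 and Areg stayed below -1 without passing and Upk3a kept 0 counts in the Pik3caH1047R cells. Clusters 0 and 21, both rich in Csn3, held 20.81 and 22.72 CPM of Areg and 5.71 and 6.33 CPM of Esr1. Macrophage-like clusters 1 and 4 held 18.06 and 23.61 CPM of Areg and 2.65 and 4.39 CPM of Esr1. Folds of Areg and Esr1 in the milk gene clusters are thus not told apart from background.

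**Figure D4:**
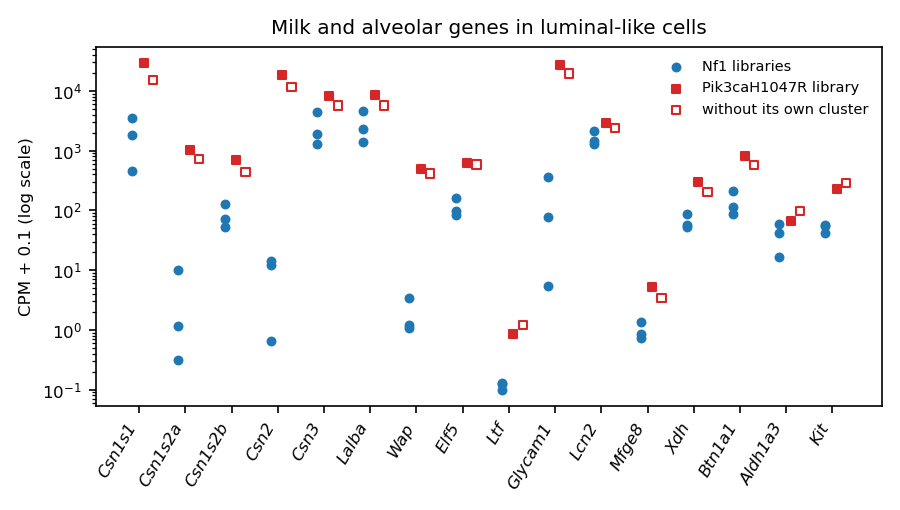
CPM (plus 0.1, log scale) of the 16 milk and alveolar genes in luminal-like cells, as points for 3 Nf1 libraries and the Pik3caH1047R library with and without its own cluster of 52 cells. Wap stands at 487.8 CPM with that cluster and 413.9 CPM without it, against at most 3.27 CPM in the Nf1 libraries.

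Fibroblast-like cells were compared next (48 Pik3caH1047R cells against 65 and 49 Nf1 cells). This fit had 1 residual degree of freedom, so its spread is pooled across genes, and neither Nf1 sum could be left out. It was not simulated, and DESeq2 called 684 genes where edgeR called 2585, so its p-values are weak evidence. Col3a1 was higher in the Pik3caH1047R cells by 4.05 ± 0.15 (adjusted p = 2.01e-13) and Col1a2 by 3.31 ± 0.15 (2.12e-12), and so was Cxcl12, a chemokine of stromal cells, by 4.48 ± 0.32 (1.68e-09). Fosb rose by 5.66 ± 0.24 and Fos by 5.18 ± 0.23, both at 1.7e-12. Dusp6 was lower at -4.05 ± 0.36 (2.77e-08). Nf1 at -0.08 ± 0.26 (0.844) and Pik3ca at 0.38 ± 0.26 (0.302) did not pass. Prlr stood at -2.41 ± 0.64 (0.0075) and Esr1 at -0.99 ± 0.37 (0.0495). Prlr averaged 89.35 CPM in Nf1 fibroblast-like and 1388 CPM in Nf1 epithelial-like cells, and 10 luminal markers stood in the former at 4.74 to 12.3% of their epithelial-like level, so this Prlr is not told apart from background. Pgr was at least 5.78-fold lower, with 0 counts in the Pik3caH1047R cells.

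Of 8951 genes 2585 passed, 1487 higher and 1098 lower. Of 14 stress genes 11 rose with none lower, the same adjusted over the list alone (adjusted p = 2.24e-20, and 0.581 with an estimated correlation). Matrix genes rose in 11 of 23 and fell in 2 (11 and 3 adjusted over the list alone; 6.86e-07, and 0.581 with an estimated correlation). Glycolysis genes fell in 10 of 18 and rose in 3, with Eno1, an enolase, at -2.30 ± 0.29 (3.38e-06), and FOXO targets rose in 5 of 13 with none lower, both the same adjusted over the list alone (0.00781 and 0.0213, each 0.581 with an estimated correlation). Ras-MAPK output genes fell in 6 of 15 and rose in 1 (2 and 7 adjusted over the list alone; 0.0376, and 0.581 with an estimated correlation).

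Hormone receptors and targets rose in 6 and fell in 9 of 18 (6 and 12 adjusted over the list alone; 0.726). Tumour macrophage genes rose in 5 and fell in 2 of 10 (6 and 4 adjusted over the list alone; 0.2201), and growth factor genes in 5 and 4 of 16 (6 and 5 adjusted over the list alone; 0.270), with Igf1 at 4.89 ± 0.30 (1.44e-10). Milk genes rose in 4 and fell in 3 of 11 (0.749), sterol genes in 1 and 4 of 14 (0.148), MHC genes in 1 and 5 of 18 (0.148) and T cell genes in 2 and 0 of 4 (0.148). Cell cycle genes had 0 of 11 past the threshold by edgeR, 1 at an unadjusted p under 0.05 and 0 by DESeq2 (0.726), and edited and driver genes rose in 2 and fell in 3 of 11. These counts were the same adjusted over the list alone. Zfpm2 was at least 397-fold higher and Zfp804b at least 131-fold lower. Esr1 did not pass by DESeq2 (0.847), with DESeq2 size factors (0.0579), without the expression filter (0.0555), without cell filters (0.0678) or at a limit of 10% mitochondrial UMIs (0.0883), in a range of 0.0114 to 0.847, with folds of -0.95 to -1.12. Prlr did not pass by DESeq2 (-2.33, 0.234), without cell filters (-3.17, 0.0873) or at 10% mitochondrial UMIs (-1.04, 0.171), in a range of 1.39e-06 to 0.234. By DESeq2 Pgr (0.125, in a range of 2.35e-05 to 0.125) did not pass either.

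Macrophage-like cells of the Pik3caH1047R library (157 cells, 1025154 UMIs) were set against those of the 3 CD45-positive Nf1 libraries (1042, 1087 and 2421 cells). Tnf was higher in the Pik3caH1047R cells by 2.76 ± 0.15 (adjusted p = 0.000938), Ccl2, a monocyte chemoattractant, by 3.21 ± 0.21 (0.00108) and Nr4a1 by 3.32 ± 0.08 (0.000143). The glycolytic enzymes Tpi1, at -2.39 ± 0.15 (0.00108), and Ldha, at -1.90 ± 0.13 (0.00123), were lower. Nf1 at 0.26 ± 0.11 (0.147) and Pik3ca at 0.26 ± 0.11 (0.264) did not pass. Csn2 was higher by 9.12 ± 0.23 (0.000143), at 200.9 CPM of summed UMIs against at most 0.519 CPM in the Nf1 libraries, in a library whose luminal-like cells held 18690.0 CPM. Of these 206 Csn2 UMIs 111 (53.9%) lay in 2 of the 157 cells, so this is not a level of the class.

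In all 3210 of 13975 genes passed, 1723 higher and 1487 lower. Stress genes rose in 8 and fell in 2 of 15, and tumour macrophage genes rose in 6 of 19 with none lower, both the same adjusted over the list alone (adjusted p = 0.00545 and 0.0253, each 0.677 with an estimated correlation). Glycolysis genes fell in 11 and rose in 3 of 20 (4 and 12 adjusted over the list alone; 0.00227, and 0.677 with an estimated correlation). Cell cycle genes fell in 11 and rose in 1 of 29 (1 and 17 adjusted over the list alone; 0.00111, and 0.677 with an estimated correlation), Cdk1 at least 11.0-fold lower. The compared cells differ in kind: cluster 16, where Mki67 stood at 908.5 CPM, held 3.94%, 9.20% and 9.87% of the Nf1 but 0.637% of the Pik3caH1047R macrophage-like cells. Clusters 19 and 35 held 30.6% and 19.8% of the latter, against at most 9.02% and 0.768% in an Nf1 library. Matrix genes rose in 7 of 23 with none lower (8 and 0 adjusted over the list alone; 0.00227, and 0.677 with an estimated correlation), Col3a1 at 5.71 ± 0.22 (0.000373) with the levels in other classes given above. Milk genes rose in 5 and fell in 3 of 13 (6 and 3 adjusted over the list alone; 0.0298, and 0.677 with an estimated correlation).

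Hormone receptors and targets fell in 5 of 20 with none higher (2 and 5 adjusted over the list alone; 0.578), Prlr at -3.37 ± 0.37 (0.00393); a Prlr UMI was found in 9.80 ± 1.64% (SD, n = 3) of Nf1 macrophage-like cells and 0.735% of Pik3caH1047R ones. FOXO targets rose in 5 and fell in 1 of 15 (6 and 2 adjusted over the list alone; 0.126), and MHC genes in 4 and 5 of 26 (4 and 6 adjusted over the list alone; 0.706). Ras-MAPK output genes rose in 5 and fell in 5 of 17 (0.951), sterol genes in 3 and 1 of 20 (0.455), growth factor genes in 3 and 4 of 20 (0.788), T cell genes in 2 and 0 of 14 (0.455) and edited and driver genes in 3 and 2 of 12. These counts were the same adjusted over the list alone. Mcpt1 and Otos were at least 5.82-fold and 5.53-fold lower. Mcpt1 is a leading gene of the mast-like cluster, and the Pik3caH1047R library held 0 mast-like cells. Otos is the first leading gene of a luminal-like cluster.

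Without Nf1 replicate 2 the count was 1835, and without cells holding UMIs of another compartment it was 1558. In the latter setting Cdk1 (adjusted p = 0.0785, in a range of 8.75e-05 to 0.0785) did not pass, and Mcpt1 did not at a limit of 10% mitochondrial UMIs (0.186, in a range of 0.000465 to 0.186). Both genes had no counts in the Pik3caH1047R cells of the main fit, so their fitted folds measure no size. Only the floors given above do.

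T-like cells of the Pik3caH1047R library (371 cells, 1503458 UMIs) were set against those of the CD45-positive Nf1 libraries (969, 374 and 594 cells). Top2a, a topoisomerase of dividing cells, was lower in the Pik3caH1047R cells at -3.10 ± 0.25 (adjusted p = 5.81e-06), as was Ube2c at -4.14 ± 0.38 (1.44e-05). Cluster 15, where Mki67 stood at 1068 CPM, held 17.8%, 26.5% and 29.0% of the Nf1 but 1.35% of the Pik3caH1047R T-like cells. Costimulatory receptors Tnfrsf18 (GITR) and Tnfrsf4 (OX40) were lower at -2.97 ± 0.17 (9.21e-07) and -3.73 ± 0.22 (9.26e-07), and Il2ra, the interleukin-2 receptor alpha chain, was higher by 1.25 ± 0.10 (6.34e-06). Nf1 rose by 1.18 ± 0.15 (0.000113) and Pik3ca by 1.26 ± 0.13 (3.18e-05) in these cells. Of the Pik3caH1047R cells 334 of 371 lay in cluster 17, which held 24, 7 and 5 of the Nf1 cells, so the compared cells differ in kind as well as in tumour.

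The edgeR test passed 5179 of 12128 genes, 2689 higher and 2490 lower. Cell cycle genes fell in 26 of 29 with none higher (1 and 28 adjusted over the list alone; adjusted p = 1.53e-10, and 0.616 with an estimated correlation). FOXO targets rose in 10 of 15 with none lower (0.000464), Igf1r at 3.22 ± 0.22 (2.17e-06) and Klf6 at 2.01 ± 0.17 (1.02e-05) among them. MHC and interferon genes fell in 11 and rose in 2 of 24 (0.0233), Mx2, an interferon-induced GTPase, at -4.26 ± 0.33 (4.7e-06) among them. Matrix genes rose in 13 and fell in 2 of 18 (5.93e-07), Col3a1 at 6.69 ± 0.22 (5.65e-08) among them. Its levels in the epithelial-like and T-like cells of this library, given above, were of similar size. Matrix transcripts in T-like cells are thus not told apart from RNA of other cells. For these 3 lists the counts were the same adjusted over the list alone, and each had adjusted p = 0.329 with an estimated correlation. Stress genes rose in 9 and fell in 2 of 14 (10 and 2 adjusted over the list alone; 0.00408, and 0.329 with an estimated correlation), Nr4a1 at 3.73 ± 0.15 (1.24e-07) among them.

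T cell activation genes rose in 6 and fell in 11 of 20 (0.101). Hormone receptors and targets rose in 6 and fell in 8 of 20 (0.266), Prlr at -3.51 ± 0.42 (8.32e-05); without cell filters (0.0764) and with doublets kept (0.126) Prlr did not pass, in a range of 5.74e-20 to 0.126. Milk genes rose in 3 and fell in 2 of 13 (0.902), Csn2 at 6.22 ± 0.41 (1.81e-06). Sterol genes rose in 3 and fell in 3 of 20 (0.902), tumour macrophage genes in 6 and 3 of 17 (0.242) and growth factor genes in 3 and 6 of 13 (0.902). These counts were the same adjusted over the list alone. Ras-MAPK output genes rose in 5 and fell in 5 of 17 (6 and 5 adjusted over the list alone; 0.955), glycolysis genes in 3 and 9 of 19 (6 and 9 adjusted over the list alone; 0.101) and edited and driver genes in 5 and 4 of 12 (5 and 5 adjusted over the list alone). Cpxm1 rose by 6.86 ± 0.50 (3.59e-06), and Oasl, an interferon-induced gene, was at least 12.9-fold lower. DESeq2 called 3240 genes, and Pik3caH1047R cells with a clear leading tag gave 3282 genes.

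**Figure D5:**
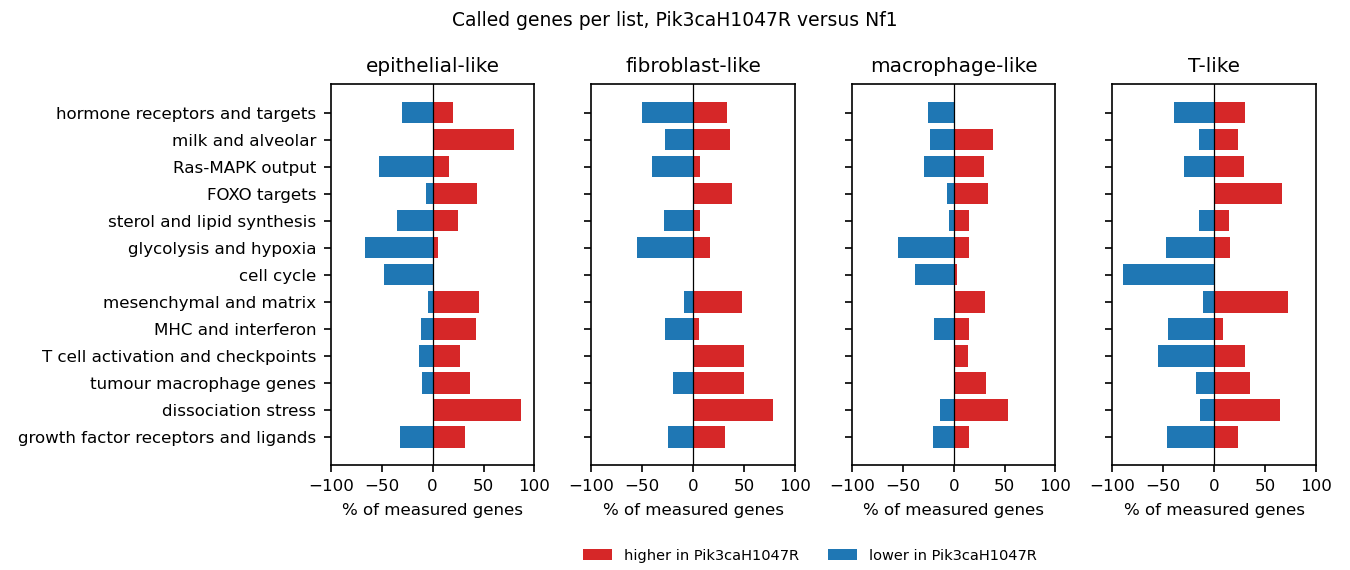
Share (%) of measured members of each list that were higher or lower in the Pik3caH1047R library, in 4 cell classes. Stress genes rose in 13 of 15 in epithelial-like, 11 of 14 in fibroblast-like, 8 of 15 in macrophage-like and 9 of 14 in T-like cells.

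Whether a genotype difference depends on the cell class was tested with an interaction term for the 8 genes fixed beforehand. The Nf1 epithelial-like sums came from CD45-negative libraries and the T-like and macrophage-like ones from CD45-positive libraries. Class and fraction thus cannot be told apart in Nf1. No block was fitted, though all Pik3caH1047R sums came from 1 library. In summed UMIs Prlr stood at 40.16 CPM in Nf1 macrophage-like and 48.04 CPM in Nf1 T-like cells, so neither is told apart from background. Prlr was lower in the Pik3caH1047R library by more in T-like than in epithelial-like cells (difference -3.57 ± 0.50 on the log2 scale, adjusted p = 0.00587) and also in macrophage-like cells (-3.39 ± 0.47, 0.0107). In Nf1 T-like cells Prlr is read above as background, at 47.45 CPM, and its fall there stood at -0.68 (adjusted p = 0.0764) without cell filters and -0.51 (0.126) with doublets kept, in a range of 5.74e-20 to 0.126 over the alternatives. Without cell filters Prlr fell by 2.90 in epithelial-like and 3.51 in macrophage-like cells, so the class difference turned in sign for T-like cells and shrank for macrophage-like cells; the interaction was not tested in that setting. Erbb2 was higher by more in T-like (2.36 ± 0.54, 0.0246) and macrophage-like cells (2.03 ± 0.43, 0.0335) than in epithelial-like cells. The rise of Erbb2 was 3.54 ± 0.60 in T-like and 3.17 ± 0.47 in macrophage-like cells. It did not pass in T-like cells with a clear leading tag (2.86, adjusted p = 0.0544, in a range of 1.61e-08 to 0.0544) or in macrophage-like cells without UMIs of another compartment (2.78, 0.0761, in a range of 0.000151 to 0.0761), where it was smaller but kept its direction. Nf1 (1.18 ± 0.16, 0.00524) and Pik3ca (0.62 ± 0.15, 0.0337) differed between T-like and epithelial-like cells, but not between macrophage-like and epithelial-like cells (0.29 ± 0.16, 0.348, and -0.36 ± 0.12, 0.193). For Esr1 the differences, -1.85 ± 1.19 (0.348) in T-like and -1.33 ± 1.18 (0.581) in macrophage-like cells, did not pass.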

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

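The tests in this part were chosen after the data had been seen, the interaction test on 8 genes fixed before. That test had no block, though all Pik3caH1047R sums came from 1 library. Its Nf1 epithelial-like and immune sums came from different fractions, so class and fraction cannot be told apart. Prlr stood at 40.16 CPM of summed UMIs in Nf1 macrophage-like cells, near the 48.04 CPM of Nf1 T-like cells. The difference between the Pik3caH1047R and the Nf1 libraries itself differed between cell classes for 4 of these genes by edgeR. Prlr differed by -3.565 ± 0.503 on the log2 scale between T-like and epithelial-like cells (adjusted p = 0.00587). Between macrophage-like and epithelial-like cells Prlr differed by -3.385 ± 0.468 (0.0107). A Prlr UMI was found in 11.6% of Nf1 T-like cells, which the text reads as background, and its fall there did not pass without cell filters (adjusted p = 0.0764) or with doublets kept (0.126), in a range of 5.74e-20 to 0.126. Without cell filters Prlr stood at -2.899 in epithelial-like against -0.675 in T-like cells, so this difference turned in sign, and no interaction was tested in that setting. Of the Pik3caH1047R T-like cells 334 of 371 lay in cluster 17, which held 24, 7 and 5 Nf1 cells, so the T-like values compare cells of different kinds. Erbb2 differed by 2.36 ± 0.536 in T-like cells (0.0246). In macrophage-like cells Erbb2 differed by 2.027 ± 0.427 (0.0335). The rise of Erbb2 was 3.535 ± 0.604 in T-like and 3.174 ± 0.474 in macrophage-like cells. It did not pass in T-like cells with a clear leading tag (2.859, adjusted p = 0.0544, in a range of 1.61e-08 to 0.0544) or in macrophage-like cells without UMIs of another compartment (2.783, 0.0761, in a range of 0.000151 to 0.0761), where it was smaller but kept its direction. Nf1 differed by 1.177 ± 0.160 in T-like cells (0.00524). Pik3ca differed by 0.619 ± 0.154 in T-like cells (0.0337). In macrophage-like cells neither passed (0.29 ± 0.159, 0.348, and -0.358 ± 0.116, 0.193).

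A signal outside the gene counts was found in the multiplexing tags. In the Pik3caH1047R library tag 302 was the highest tag in 240 cells (18.1%), beside tag 301 in 1083 cells (81.8%), while in each Nf1 library a single tag was highest in 99.86% or more of the cells. The labels do not say whether the cells of both tags belong to the same sample, and 776 of 1324 cells have a first tag with at least 2 times the counts of the second.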

How the results depend on the processing

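The alternative with a clear leading tag was chosen after seeing the data; the cause was not tested for any change below. Counts are of genes called by edgeR unless DESeq2 is named. The DESeq2 test gave 3457 genes for epithelial-like against fibroblast-like cells (5364 by edgeR), 684 for the genotypes in fibroblast-like (2585) and 3240 in T-like cells (5179). Leaving out 1 Nf1 replicate gave 4005 to 6110 genes in epithelial-like (main 6046), 1835 to 4185 in macrophage-like (3210) and 5032 to 5607 in T-like cells, 6783 to 9478 for luminal-like against basal-like cells and 9275 to 12099 for the fractions. Macrophage-like cells without UMIs of another compartment gave 1558 genes, and Pik3caH1047R T-like cells with a clear leading tag 3282. Signs turned for Il2ra (-0.849, adjusted p = 0.626, range over alternatives 0.00187 to 0.626) and Icos (-7.077, 0.243, range 0.00994 to 0.243) in epithelial-like cells without UMIs of another compartment, for Gzmb (-7.976, 0.432, range 3.34e-06 to 0.432) and Gzma (-1.609, 0.249, range 0.00336 to 0.422) in macrophage-like cells with doublets kept, and for Erbb4 in T-like cells without cell filters (1.093, 0.0023) and with doublets kept (1.174, 0.00138, range 1.42e-16 to 0.0023), where it passed in the other direction. Of 5785 values of 451 named genes under alternatives, 5622 kept direction and side of the threshold, 120 no longer passed, 24 newly passed, 6 turned and 13 without a call changed sign; 362 genes kept both throughout.

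The epithelial-like share of the CD45-negative libraries was 69.43% without cell filters, 88.73% at resolution 2.0 and 95.06% with readout genes in clustering; in the Pik3caH1047R library it was 8.939% without cell filters, 15.82% at most 10% mitochondrial UMIs and 11.92% at resolution 2.0. T-like and NK-like cells there were 44.02% without cell filters and 53.52% at most 10% mitochondrial UMIs. The Nf1 share with Esr1 was 10.83% at most 10% mitochondrial UMIs, 14.32% at resolution 2.0, 8.068% thinned to 1000 UMIs and 34.53% without thinning. The Pik3caH1047R share was 2.586% without cell filters, 19.69% at resolution 2.0 and 25.76% without thinning. Its luminal-like share at resolution 2.0 was 10.83%, and thinning was drawn separately for each class, so the 19.69% is not told apart from the draw. With an estimated correlation camera called 0 lists in each of the 7 comparisons (at an unadjusted p, 2 for the fractions, 1 in T-like cells and 0 in the others). By themselves these losses do not show that correlated genes made the calls. For some called lists of the genotypes the estimate lay far above the preset. It was 0.855 for stress and 0.621 for milk genes in epithelial-like cells, and 0.721 for cell cycle genes in T-like cells. Preset p-values of such lists can be too small and are weak evidence. For stress genes in fibroblast-like cells of the genotypes the estimated correlation was 0.011, near the preset 0.01. There the unadjusted p by camera still went from 1.72e-21 to 0.0668. By fry 0 lists passed for epithelial-like against fibroblast-like cells (7 at an unadjusted p, and 6 by camera), 11 for luminal-like against basal-like cells (7 by camera), 2 for the genotypes in fibroblast-like (5 by camera) and 2 in macrophage-like cells (6 by camera). The cell cycle (0.222), glycolysis (0.120) and MHC lists (0.0501) in epithelial-like cells and the cell cycle list (0.0893) in T-like cells, all called by camera, did not pass by fry. Fry alone called FOXO targets (0.0198), tumour macrophage (0.0198), T cell (0.0320) and growth factor genes (0.0320) in epithelial-like cells, growth factor genes (0.0441) in T-like and T cell genes (0.0329) in fibroblast-like cells. The tumour number as a block for the fractions gave 11687 genes and changed the call of the matrix list and of no gene named in this text. Without the block 5570 genes passed for epithelial-like against fibroblast-like and 9145 for luminal-like against basal-like cells, where 4 lists were called and Ccnb1, Cenpf and Bub1b no longer passed. No paired analysis was possible for the genotypes because the Pik3caH1047R library has no partner. Fits not run, for want of sums or residual degrees of freedom, were those with fibroblast-like cells without UMIs of another compartment or without Nf1 replicate 2 or 3, and the genotypes in fibroblast-like cells without replicate 1, which had no sum. Sums thinned to the total of the Pik3caH1047R library gave 4480 of 12707 tested genes in epithelial-like (main 6046 of 16928), 2431 of 9514 in macrophage-like (3210 of 13975), 4591 of 10196 in T-like (5179 of 12128) and 2784 of 8931 in fibroblast-like cells (2585 of 8951).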

Other observations

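Luminal-like cells of the Nf1 tumours fell into clusters that differed in Esr1 and Csn3. Clusters 0 and 21 held 5.71 and 6.33 CPM of Esr1 beside 5800.0 and 6294 CPM of Csn3, while Esr1 stood at 298.8 CPM in cluster 5, 203.6 CPM in cluster 7 and 119.4 CPM in cluster 3. Cluster 28 held 115.7 CPM of Esr1 and 2383 CPM of Csn3, but its median UMI count was 2.09 times that of the cells' libraries, and 13, 2 and 11 of its 84 cells came from the CD45-positive libraries; remaining doublets were not tested there. Cluster 7 held 884 cells of tumour 1 (42.2% of its luminal-like cells) but 9 and 29 cells of tumours 2 and 3, and cluster 3 held 35, 893 and 654 cells of the 3 tumours. In the Pik3caH1047R library 102 of 191 luminal-like cells lay in cluster 0, and 52 formed cluster 36, which no Nf1 library shared and where Csn2 stood at 33400.0 CPM. Of its macrophage-like cells 30.6% and 19.8% lay in clusters 19 and 35, against at most 9.02% and 0.768% in the CD45-positive Nf1 libraries.

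All tests in this part were chosen after the result had been seen, except the doublet test over both immune classes together. Milk transcripts were found outside epithelial cells of the Pik3caH1047R library, with Csn2 at 42.6 CPM in T-like and 200.9 CPM in macrophage-like cells. Doublets are argued against in T-like cells, where 0.0% of Csn2 UMIs lay in cells with 10 or more; over both classes the share was 41.11%, between the bounds set, and in macrophage-like cells it was 53.88%, in 2 cells, as doublets would give. Free RNA could hold too: Glycam1 per Csn2 UMI, relative to luminal-like cells, was 0.916 (95% interval 0.655 to 1.29) in T-like and 1.00 (0.837 to 1.20) in macrophage-like cells, but 0.386 (0.200 to 0.723) in fibroblast-like cells, an interval that crosses the bound. For Csn2 of the luminal-like cells free RNA is argued against, since outside cluster 36 it was 273.4 times that in T-like cells. A part of the cells carries that mean, as 79 of all 191 luminal-like cells held 99.86% of the Csn2 UMIs. Cluster 36 alone does not carry the milk genes, since 11 of 12 called ones stayed over 2 times every Nf1 library without it, Lcn2 excepted. Of the 139 luminal-like cells left, 102 lay in cluster 0, which is rich in Csn3. Genotype and a stage of the gland that the labels do not give stay open and untested. The make-up of the luminal-like cells stays open too. Clusters rich in Csn3 were compared alone between the genotypes, but milk gene folds from that fit are not reported here.

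Stress genes rose in the Pik3caH1047R library in 4 of 4 classes by camera with the preset correlation and in 0 of 4 with an estimated one (adjusted p = 0.329 to 0.677). The latter setting called no list in any comparison, so it cannot decide this. The estimate was 0.855 in epithelial-like cells, where the preset p-value can thus be too small. In fibroblast-like, macrophage-like and T-like cells it was 0.0110 to 0.0149, near the preset. Lower depth is argued against, since 13 of 13 called genes of the epithelial-like cells were called higher with sums thinned to that library's total. Handling, date and genotype cannot be told apart, because a single library carries all of them.

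Esr1 stood in fibroblast-like cells of the Nf1 tumours at 102.7% of its epithelial-like level. That level includes basal-like cells at 3.87 CPM. Luminal-like cells averaged 105.5 CPM over 3 tumours, against 83.05 CPM in fibroblast-like cells of 2. Free RNA or doublets from epithelial cells are argued against, since 10 luminal markers stood there at a median of 8.717% of their epithelial-like level (4.74 to 12.3%). No biological explanation was tested.

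The 6 libraries of the 2 fractions can be split in 10 ways, too few for a share under 0.05: the real split called 11924 genes by edgeR and the highest other 0 (170 at an unadjusted p). It parts the 3 numbered pairs, as do 3 others, which called 0 (29 to 146 at an unadjusted p). For the 6 luminal-like and basal-like sums the real one of 10 splits, again too few, called 9049 genes and the highest other 0 (167 at an unadjusted p), and the 3 others that part all pairs 0 (5 to 34). The fractions were sorted to hold different cells, and the classes were made by clustering these same cells. The real split thus had to call far more genes than the others, and neither result is support.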
